A study of Homo sapiens with 4 samples.

How the data were processed

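Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in untreated MCF-7 cells, an oestrogen receptor-positive luminal breast cancer line. The series holds 4 samples: 1 ChIP library each for GATA3, G9A and MTA3, and 1 input DNA library. Per the labels' protocols, ChIP DNA was end-polished, ligated to Illumina adaptors, amplified by PCR and cut from a gel before sequencing on a HiSeq2000. The submitters' processing notes name CASAVA 1.4, Bowtie 0.12.8 and MACS, a program that finds places where reads pile up above background, and the build GRCh37. The MACS version, the read filters and whether the input library served as the control are not given in the sources used here. Each ChIP sample has its own peak list, so libraries were not pooled.

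For each ChIP library the authors deposited a list of peaks and a list of 1 summit per peak. The deposited peak list gives each peak's start, end and score, and this score is the authors' own value. It is read here as MACS's 10 times the negative log10 of the p-value, from the layout of the lists and from smallest values close to 50. The deposited summit list gives a signal, a whole number read here as the height of the read pileup at the summit, with no normalization. Scores and heights were therefore used to rank, filter or describe the peaks of each list. Numbers of peaks past a fixed score or height are given for each list, and differences in them between lists can come from depth. Every summit lay inside its peak, and no peaks of one list overlapped each other. Positions are printed counting from 1.

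The labels and the file names disagree for a pair of samples. The sample labelled GATA3 carries files named for G9A, and the sample labelled G9A carries files named for GATA3. Samples were grouped by their labels, and every library is called by its label below. A check of the GATA motif under the summits was planned for this reason and was not run, because it needs GRCh37 sequence. No genome or annotation of GRCh37 was used here, and the gene table at hand is of GRCh38. The planned results on motifs, promoters, target genes and gene lists are therefore not reported, and the regions named below carry positions in place of gene names.

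Total reads per library were not among the files, so the depth is unknown. The median summit height was 5 or 6, and a height of 5 has an exact Poisson 95% interval of 1.62 to 11.7 reads. Intervals on shares of peaks are exact (Clopper-Pearson) at 95% and cover counting error only, as PCR duplicates and neighbouring peaks are not independent. With 1 library per target there is no replicate check of any value, and differences between libraries compare those libraries, not the proteins.

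Overlap was counted as at least 1 bp shared between peaks. The overlap of each pair was set against 1000 random placements of the second library's peaks on their own chromosomes, with widths kept; for regions of all 3, the MTA3 peaks stayed and the others were placed. The largest peak end on a chromosome over the 3 lists stood in for its length. Uniform placement also reaches centromeres and other sequence where no peak can be called, so a second kind of placement moved each of these peaks by 10 to 50 kb to a random side. Regions were made by merging all peaks that share at least 1 bp. Such placements of both other libraries also break the overlap of each pair. The number of MTA3 peaks that overlap both was therefore also set against 1000 permutations of the G9A overlap among MTA3 peaks of one chromosome or of one group of ranks, which keep the overlap of MTA3 with each library but not that of G9A with GATA3. Distances between summits of overlapping peaks were set against summits redrawn uniformly inside the same peaks 1000 times. Median scores of peaks in regions of all 3 libraries and of peaks of 1 library alone were compared by 10000 two-sided permutations of the peak classes within a library. Peaks within a library are not replicates, so these p-values describe that list only.

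The alternatives were an overlap of 50% of both peaks, summits within 100 bp, peaks with a score of at least 100, the 5000 highest peaks of each library, leaving out chromosomes 1, 3, 17 and 20, peaks less than 1 kb apart merged, the labels exchanged, only peaks narrower than the median for summit distances, and height or score per kb of width in place of score. Under the 50% and the 100 bp rules, sharing by all 3 was counted as MTA3 peaks with partners that met the rule for each pair. Named peaks followed a rule: the 8 highest peaks of each library by score (ties by height), and the 20 regions of all 3 libraries with the lowest sum of within-library ranks. These choices, and the tests of overlap, summit distance and score, were made before the data were examined. The shares per chromosome, the shares of regions with a further library, the groups of ranks, the 1 Mb bins these permutations and the alternatives that leave out such bins or the highest GATA3 peaks were chosen afterwards. The overlap code was tested on simulated data built on the GATA3 and MTA3 lists (17662 peaks): with 1000 shared peaks planted it found 1123 overlaps, against a placement mean of 146, or 985 above the chance expected for the peaks not planted, and with none planted it found 131 against a highest placement of 176. On scores drawn from the MTA3 list, the median test called 7 of 100 draws with no shift and 100 of 100 with a planted shift of 20%. Smaller shifts were not tried. Both checks used fewer placements or permutations than the tests above, and the scores were drawn independently, unlike those of neighbouring peaks. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.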

Results

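The data are peak lists from ChIP-seq of 3 chromatin proteins in untreated MCF-7 cells. GATA3 is a zinc-finger transcription factor of luminal breast epithelium. G9A (EHMT2) is a histone H3 lysine methyltransferase that places repressive marks, and MTA3 is a subunit of the nucleosome remodelling and deacetylase (NuRD) complex. By its title and design text, the series asks which genomic targets the 3 proteins have and share. Each target had 1 library, and the input DNA library was not analysed here. Because labels and file names disagree for the GATA3 and G9A samples, each value below belongs to "the library labelled" so, and any direction between those libraries turns round if the file names are right.

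The library labelled MTA3 had 17846 peaks, the library labelled GATA3 17662 and the library labelled G9A 10422. A score of at least 100 was reached by 4356 peaks in the list labelled GATA3, 3642 in that labelled MTA3 and 1021 in that labelled G9A, and a score of at least 300 by 740, 102 and 4. A summit height of at least 10 was reached by 3278, 2715 and 209 peaks, and of at least 50 by 171, 31 and 4. Most peaks in every list were low: the median score was 72.7 for GATA3 (interquartile range 59.0 to 99.6), 67.9 for G9A (59.3 to 81.4) and 71.9 for MTA3 (60.9 to 93.1), and the median height was 6, 5 and 6. Median peak width was 561 bp, 499 bp and 546 bp, and the peaks covered 11.0, 5.40 and 11.0 Mb. Sequencing depths are unknown and the values are not normalized, so these numbers describe each list and do not rank the libraries.

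The strongest peaks of the library labelled GATA3 were mostly its own. The highest by score stood on chromosome 12 from 175256 to 177183 with a score of 3184.55 and a height of 183. GATA3 ranks 2 to 6 and the highest MTA3 peak all had a score of exactly 3100. It is not a ceiling of all scores, as the first GATA3 peak passed it, and why it recurs was not tested. The order of these GATA3 peaks by score may therefore not be a measured one, and some of them were taller than the first. On chromosome 3 a peak from 10501491 to 10503112 reached a score of 3100 and a height of 212, and another from 62514811 to 62515855 reached a height of 177. Of its 8 highest peaks, 6 overlapped no peak of another library, and 1, on chromosome 7 from 154861040 to 154862497, overlapped peaks of both. The library labelled MTA3 was the opposite: all of its 8 highest peaks overlapped peaks of both other libraries. These included a pair on chromosome 17, from 57921964 to 57924614 (score 1479.91, height 97) and from 57914481 to 57916399 (score 1056.18, height 73). Another 4 stood on chromosome 20, from 49377824 to 49378800, from 49407020 to 49408061, from 52205183 to 52214905 and from 52237839 to 52241093. Chromosomes 17 and 20 carry amplified segments in MCF-7. The highest MTA3 peak lay in a segment of chromosome 1 that resembles mitochondrial DNA, and 1 stood on chromosome 13. Whether extra copies or such sequence account for the overlap of these MTA3 peaks was not tested. In the library labelled G9A, 6 of the 8 highest peaks overlapped both others, but 3 of these lay in the same segment of chromosome 1. Its highest lay on chromosome 15 from 25537037 to 25537940, with a score of 1095.63 and a height of 252. Its peak on chromosome 7 from 113517664 to 113519569 had a score of 242 at a height of 8 and overlapped none. The chromosome 1 segment, from 564022 to 570456 and known to hold a nuclear copy of mitochondrial DNA, held a peak among the 12 highest peaks of each library.

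The library labelled G9A was spread over the chromosomes unlike the others. It had 13.5% of its peaks on chromosome 3 (95% interval 12.9 to 14.2) and 12.5% on chromosome 7 (11.9 to 13.2). The corresponding shares were 6.92% (6.55 to 7.31) and 6.49% (6.13 to 6.86) for GATA3, and 7.61% (7.22 to 8.01) and 7.87% (7.48 to 8.27) for MTA3. On chromosome 19, the most gene-dense human chromosome, it had 0.825% of its peaks (0.661 to 1.02), against 3.23% (2.97 to 3.50) for GATA3 and 3.81% (3.53 to 4.10) for MTA3. Chromosome 22 held 0.355% (0.250 to 0.489), against 1.25% (1.09 to 1.42) and 1.13% (0.982 to 1.30). In density, chromosome 19 carried 1.46 peaks per Mb in the library labelled G9A, 9.65 in that labelled GATA3 and 11.5 in that labelled MTA3. The share of G9A peaks on chromosome 19 was 0.680% (34 peaks) among its 5000 highest, and 0.196% among those with a score of at least 100, which rests on 2 peaks. The intervals of G9A lay outside those of both other libraries on chromosomes 3, 7, 19 and 22. The same held on chromosomes 4, 8, 9, 10, 15, 16, 17 and 21, so the difference is not particular to the chromosomes described. These intervals cover counting error only. Whether gene density or base composition goes with these shares was not tested.

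**Figure D1:**
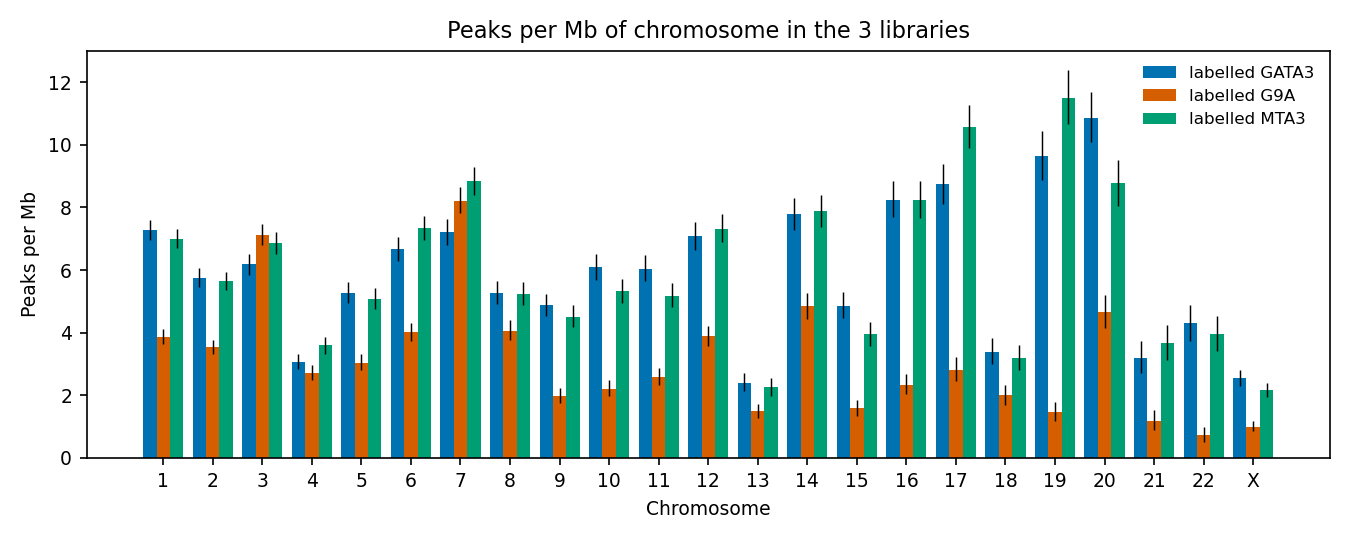
Bars give peaks per Mb of each chromosome (x axis) in the libraries labelled GATA3, G9A and MTA3, and error bars are exact 95% intervals of the peak count. On chromosome 19 the density was 9.65 for GATA3, 1.46 for G9A and 11.5 for MTA3, while on chromosome 3 it was 6.18, 7.13 and 6.86 and on chromosome 7 it was 7.21, 8.22 and 8.83.

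GATA3 and MTA3 peaks coincided most often. Of the peaks labelled GATA3, 4274 of 17662 (24.2%, 23.6 to 24.8) overlapped a peak labelled MTA3, and 4313 of the 17846 MTA3 peaks (24.2%, 23.5 to 24.8) overlapped a GATA3 peak. Of the 10422 peaks labelled G9A, 1133 (10.9%, 10.3 to 11.5) overlapped an MTA3 peak and 859 (8.24%, 7.72 to 8.79) a GATA3 peak. Uniform random placement gave a mean of 145 overlaps for GATA3 with MTA3 (highest of 1000 placements, 190), 77.9 for G9A with MTA3 (highest 104) and 75.1 for G9A with GATA3 (highest 104). The observed overlap was thus 29.5, 14.5 and 11.4 times the mean placement. When peaks were moved by only 10 to 50 kb, the ratios were 15.9, 10.3 and 11.5, each again above all 1000 placements. Neither kind of placement takes account of sequence that draws reads in any library. These ratios therefore do not tell shared binding from such sequence. Peak numbers per 1 Mb bin (2847 bins with a peak) rose and fell together in the libraries labelled GATA3 and MTA3, with a Spearman rho across bins of 0.73. For G9A, rho was 0.20 with MTA3 and 0.01 with GATA3. Bins are not independent replicates, so no p-value is given.

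Peaks of all 3 libraries met in 534 of the 40058 merged regions. Random placement gave a mean of 1.11 such regions (highest 5), and moving peaks by 10 to 50 kb a mean of 5.88 (highest 17). These placements also break the overlap of each pair. With the overlap of MTA3 with each library kept, but not that of G9A with GATA3, the excess was much smaller: 530 MTA3 peaks overlapped both others, 1.86 times the mean of 284 when G9A overlap was permuted within chromosomes (highest of 1000, 328) and 1.42 times the mean of 373 when it was permuted within groups of MTA3 ranks (highest 413). A G9A peak was found in 12.7% (11.7 to 13.7) of the 4212 regions with both GATA3 and MTA3. It was found in 2.49% (2.23 to 2.77) of the 13383 GATA3 regions without MTA3 and in 4.43% (4.09 to 4.79) of the 13520 MTA3 regions without GATA3. Seen from the other side, 61.6% (58.3 to 64.8) of the 867 regions with GATA3 and G9A also had MTA3, against 22.0% (21.4 to 22.6) of the 16728 GATA3 regions without G9A. Chromosome 20 held 9.36% (7.03 to 12.2) of the regions of all 3 but 3.13% (2.96 to 3.30) of all regions, and chromosome 17 held 5.81% (3.98 to 8.14) against 3.77% (3.59 to 3.96). Both chromosomes carry amplified segments in MCF-7. The count of 534 depends on how sharing is defined: 239 MTA3 peaks had partners overlapping by 50% of both peaks for each pair, and 99 had all 3 summits within 100 bp.

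**Figure D2:**
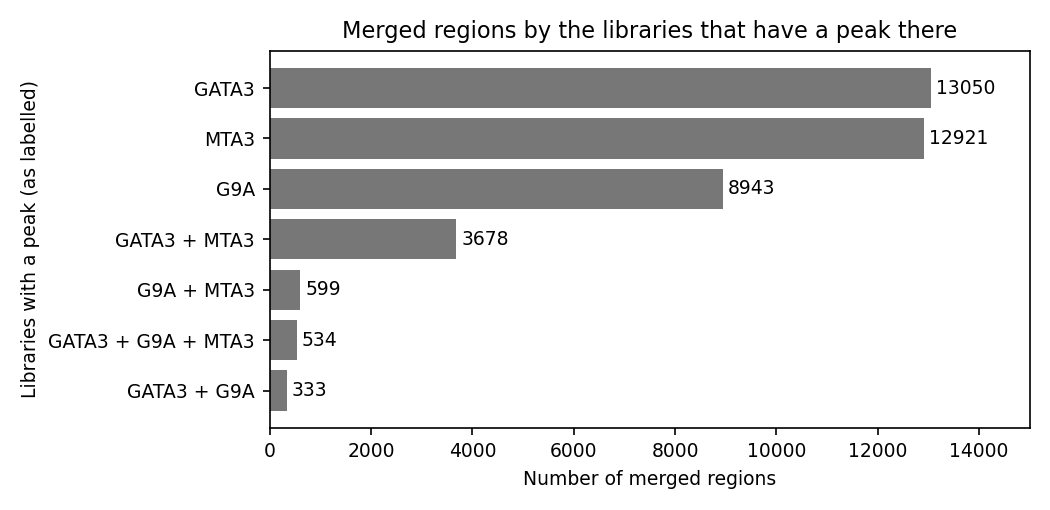
Bars give the number of merged regions (x axis) for each combination of libraries with a peak there, by label (y axis). Regions of 1 library dominate, with 13050 for GATA3, 12921 for MTA3 and 8943 for G9A, while 3678 regions had GATA3 and MTA3 and 534 had all 3.

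Of the 20 shared regions with the best ranks, 6 were on chromosome 20, 5 on chromosome 17 and 4 on chromosome 1. Another 2 were on chromosome 3. These are the chromosomes left out below as amplified. Whether extra copies of the DNA favoured these regions was not tested. After the mitochondrial-like segment of chromosome 1, the best was on chromosome 17 from 57921955 to 57924614, with scores of 757 in the library labelled GATA3, 168 in that labelled G9A and 1479.91 in that labelled MTA3. A region on chromosome 20 from 52486004 to 52487187 had scores of 560, 193 and 376, and its 3 summits spanned 63 bp. Another on chromosome 20, from 49377812 to 49378859, had scores of 406, 321 and 967 and summits within 56 bp. The region from 52738182 to 52740987 on the same chromosome had scores of 711, 128 and 415. On chromosome 3 a region from 63213823 to 63214760 had scores of 520, 176 and 308, with summits within 73 bp. The narrowest region, on chromosome 13 from 110076375 to 110076847, had scores of 268, 182 and 815 and summits within 8 bp. A region on chromosome 15 from 25537031 to 25537968 had summit heights of 183, 252 and 242, the tallest of the 20 in each library. The G9A and MTA3 heights were also the largest in their whole lists. The scores of this region were 527, 1095.63 and 375. In GATA3 a height of 183 went with a score of 3184.55 on chromosome 12, and in MTA3 a height of 110 with 838.29 on chromosome 20. Why the GATA3 and MTA3 scores were low for these heights was not tested. In 8 of the 20 regions all 3 summits lay within 100 bp of each other.

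**Figure D3:**
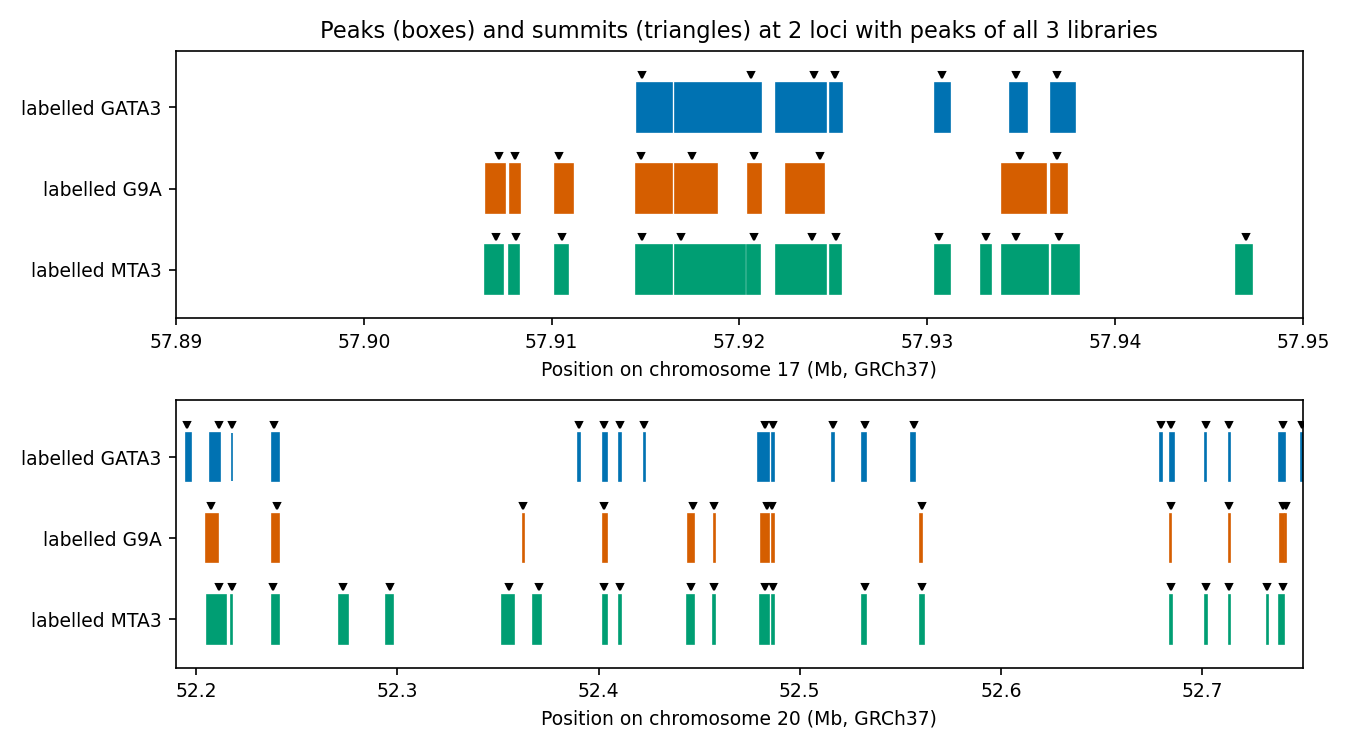
Boxes are peaks and triangles their summits along chromosome 17 from 57.89 to 57.95 Mb (upper panel) and chromosome 20 from 52.19 to 52.75 Mb (lower panel), GRCh37, with 1 row per library. The chromosome 17 window held 7 GATA3, 9 G9A and 13 MTA3 peaks, and the chromosome 20 window 19, 13 and 20.

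Where peaks overlapped, their summits lay nearer to each other than the extent of the peaks would give. The median distance was 118 bp for the 4374 overlapping pairs of GATA3 and MTA3 peaks (interquartile range 50 to 255), 132 bp for the 870 pairs of G9A and GATA3 (56 to 294) and 146 bp for the 1153 pairs of G9A and MTA3 (60 to 294). Summits redrawn inside the same peaks gave median distances of 249, 245 and 243 bp on average, and the lowest of 1000 redraws were 237, 215 and 217 bp. Within 100 bp stood 44.5% (43.0 to 46.0), 39.2% (35.9 to 42.5) and 38.0% (35.2 to 40.9) of the pairs, against 21.9%, 22.3% and 22.3% for redrawn summits. Redrawing ignores that summits may tend to lie near the middle of a peak, which was not measured here, so part of the difference can come from that.

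Shared peaks had higher scores than single ones in the libraries labelled MTA3 and GATA3, but the results for GATA3 and G9A depended on the measure. In MTA3 the median score was 106 for the 572 peaks in regions of all 3 (interquartile range 75.4 to 166) and 69.3 for the 12921 peaks of that library alone (59.9 to 86.3), with a permutation p of 0.0001, the smallest the test can give. In GATA3 it was 94.9 for 554 peaks (69.6 to 147) against 69.4 for 13050 (57.6 to 93.6), with the same permutation p of 0.0001. In G9A the medians were 69.4 for 541 peaks (58.2 to 86.0) and 67.9 for 8943 (59.6 to 81.4), a difference of 1.49 with a permutation p of 0.1863. The median G9A summit height was 6 in shared and 5 in single peaks (permutation p of 0.0114), and without chromosomes 1, 3, 17 and 20 the score difference was −1.18 (permutation p of 0.4414). Shared peaks were also wider, with medians of 749 against 519 bp in MTA3, 740 against 533 bp in GATA3 and 566 against 493 bp in G9A. Per kb of width, the sign turned round in GATA3 (−5.77, permutation p of 0.13) and in G9A (−15.6, permutation p of 0.0001), and held in MTA3 (8.56, permutation p of 0.0051).

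By rank, in groups chosen after the data were seen, overlap fell steadily in the library labelled MTA3 but peaked at middle ranks in that labelled GATA3. Of the 100 highest MTA3 peaks, 85.0% (76.5 to 91.4) overlapped a GATA3 peak and 54.0% (43.7 to 64.0) a G9A peak, and both shares were lower in every lower group of ranks, down to 16.0% (15.2 to 16.9) and 3.95% (3.53 to 4.41) below rank 10000. The median MTA3 peak width was 1327 bp in the highest group and 523 bp below rank 10000. Wider peaks have more chances to overlap, and rank was not separated from width here. Of the 100 highest GATA3 peaks, 21.0% (13.5 to 30.3) overlapped an MTA3 peak, and of those ranked above 100 up to 500, 11.3% (8.33 to 14.8), or 13.2% (10.4 to 16.5) of both groups together. The share was 41.8% (39.6 to 43.9) at ranks above 1000 up to 3000, and 17% (16.1 to 17.8) below rank 10000. Overlap with G9A peaks was 4.40% (2.78 to 6.59) at GATA3 ranks 1 to 500 and 10.9% (9.52 to 12.3) at ranks above 1000 up to 3000. Among G9A peaks, 30.0% (21.2 to 40.0) of the 100 highest overlapped an MTA3 peak and 24.0% (16.0 to 33.6) a GATA3 peak, and the shares at lower ranks were 10.0% to 14.9% and 7% to 12.3%.

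**Figure D4:**
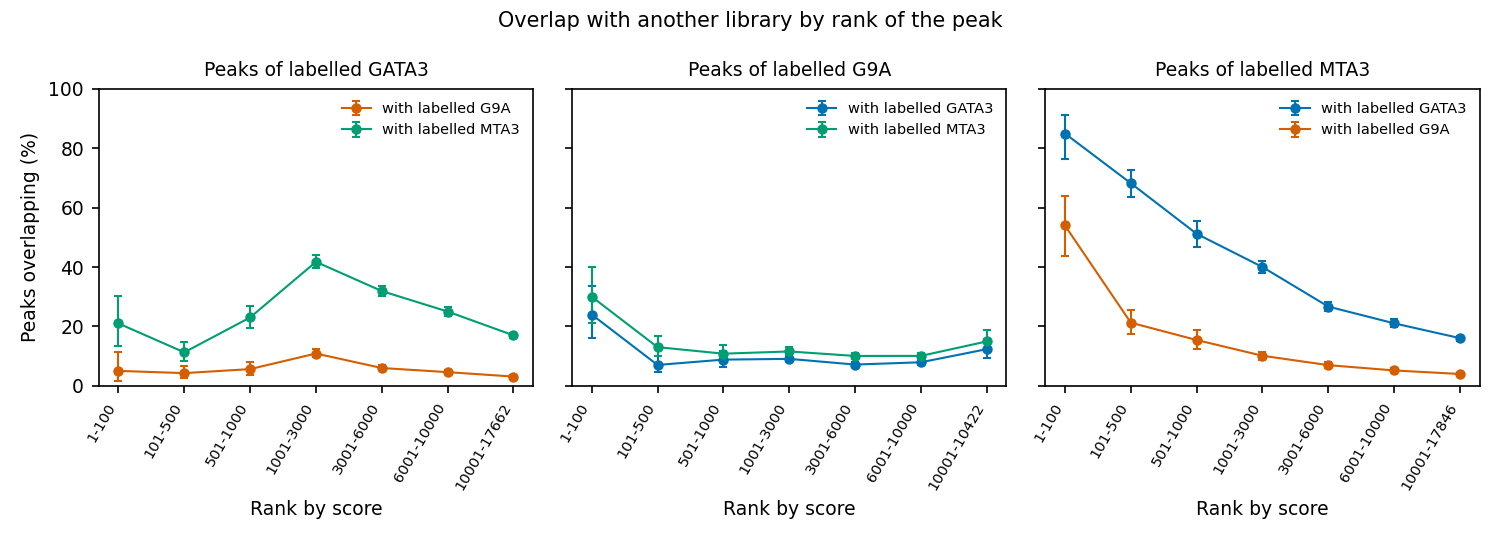
Points give the share of peaks (y axis, %) that overlap a peak of another library, by rank of score within the library (x axis), with exact 95% intervals; each panel is 1 library as labelled. Overlap of MTA3 with GATA3 falls from 85.0% at the highest ranks to 16.0%, whereas overlap of GATA3 with MTA3 is highest at ranks above 1000 up to 3000, at 41.8%.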

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

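All overlaps stayed above every one of 1000 random placements or permutations under each alternative run: the ratio to the mean placement ranged from 15.9 to 83.9 for GATA3 with MTA3, from 11.5 to 26.3 for G9A with GATA3, from 10.3 to 41.5 for G9A with MTA3, and from 90.8 to 5085 for the regions of all 3 under placements that break the pairs, with chance means as low as 0.014. Under permutations that keep the overlap of MTA3 with each library, but not that of G9A with GATA3, the ratio was 1.86 and 1.42; they were chosen after seeing the data. The random placements take no account of sequence that draws reads in any library, so an overlap above them does not by itself show shared binding. The counts moved by the construction of the settings. A score of at least 100 left 4356 GATA3, 1021 G9A and 3642 MTA3 peaks, with 725 overlaps of GATA3 with MTA3, 58 of G9A with GATA3, 83 of G9A with MTA3 and 39 regions of all 3. The 5000 highest peaks of each library gave 947, 203, 313 and 114. Summits within 100 bp gave 1946, 341, 438 and 99, and an overlap of 50% of both peaks gave 546 for G9A with GATA3, 727 for G9A with MTA3 and 239 of all 3. Without chromosomes 1, 3, 17 and 20, 754 G9A peaks overlapped MTA3 and 337 regions held all 3. Exchanging the labels gives 10422 peaks for GATA3 and 17662 for G9A. In the comparison of shared with single peaks, the difference in GATA3 turned to −5.77 per kb of width (permutation p of 0.13). In G9A, where the main difference passed no threshold, it was −15.6 per kb of width (permutation p of 0.0001), −1.18 without the 4 chromosomes (permutation p of 0.4414) and 1 in summit height (permutation p of 0.0114); the cause was not tested. Summit distances stayed below all redraws under each alternative. The alternatives for motifs, promoters, target genes and gene lists were not run. No paired analysis was possible because each target has 1 library. Low heights limit the lists: with unknown depth, a missing peak does not show that a protein is absent there.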

Other observations

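Chosen only after their results had been seen were the tests of G9A overlap and width in the 750 highest GATA3 peaks, of the share on chromosome 20 and of amplification as the whole cause (leaving out chromosomes 1, 3, 17 and 20 was itself planned), the permutations of G9A overlap among MTA3 peaks, and the settings that rank by height or leave out blocks or the highest GATA3 peaks. The tests of the blocks were fixed before their values were seen, but after the peak numbers of the densest bins. Peaks of each library were gathered in dense bins more than random placement gave. The 142 densest of the 2847 bins of 1 Mb, taken for each library, held 28.9% of the peaks labelled G9A (placement mean 14.4%, highest 14.8%), 17.1% of those labelled GATA3 (10.6%, 10.8%) and 19.3% of those labelled MTA3 (11.0%, 11.2%). Of the 142 bins of G9A, called blocks here, 42 lay on chromosome 3, 26 on chromosome 7 and 17 on chromosome 1. The densest, on chromosome 1 from 107 to 108 Mb, held 71 G9A, 27 MTA3 and 6 GATA3 peaks, and that on chromosome 7 from 113 to 114 Mb held 66, 21 and 4. The densest bin of GATA3, on chromosome 12 from 53 to 54 Mb, held 38 GATA3, 35 MTA3 and 5 G9A peaks, and that of MTA3, on chromosome 17 from 57 to 58 Mb, held 51 MTA3, 21 GATA3 and 14 G9A peaks.

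The blocks could come from the DNA of the cells, from the scoring or from the protein. Extra copies of the DNA would be present in every library, and should raise weak peaks (score under 70) in all of them. Weak MTA3 peaks were 1.70 times as dense in the blocks as in other bins (95% bootstrap interval over bins 1.47 to 1.96), but weak GATA3 peaks were 0.693 times as dense (0.568 to 0.824). The prediction thus held for MTA3 and not for GATA3. Called peaks do not measure copy number, so these values do not settle whether extra copies play a part. The 42 blocks on chromosome 3 and 17 on chromosome 1 lie on chromosomes left out elsewhere as amplified. Low local background in the scoring would give a higher score at the same height. At a height of 5 the median G9A score was 70.7 in the blocks and 70.7 elsewhere, a difference of 0. At heights of 4 and 6 the differences were −0.91 (permutation p of 0.1544) and 0.87 (permutation p of 0.3645). A clearly higher score in the blocks was thus not seen at these heights, among called peaks only. Besides extra copies, base composition and broad binding of the labelled protein stay open, and neither of the latter was tested. G9A peaks in the blocks overlapped MTA3 less often (7.54%, 6.63 to 8.55) than those elsewhere (12.2%, 11.5 to 13.0). Their overlap with GATA3 was also lower, at 3.42% (2.80 to 4.14) against 10.2% (9.52 to 10.9).

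The highest peaks of the library labelled GATA3 were less often shared than its middle ones, and the 750 highest overlapped MTA3 in 14.3% (11.8 to 17) of cases, against 41.8% at ranks above 1000 up to 3000. Ranking by height in place of score gave 19.8% for ranks 1 to 500 and 37.5% for ranks above 1000 up to 3000. These 750 peaks also overlapped G9A peaks less often than the middle group, at 4.53% (3.16 to 6.28) against 10.9% (9.52 to 12.3). Sequence that draws reads in any library, or extra DNA copies, would be expected to raise this share. However, the share is not independent of the low MTA3 overlap. A G9A peak was found in 12.7% of regions with GATA3 and MTA3, but in 2.49% of GATA3 regions without MTA3. The G9A share therefore does not settle these explanations. Narrower peaks would have fewer chances to overlap, but the median width was 819.5 bp against 666 bp. A candidate explanation is a class of GATA3 sites with little MTA3, but a wrong label, by which the 740 peaks with a score of at least 300 would be sites of another protein, cannot be told apart from it without GRCh37 sequence for the motif test.

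To test whether the regions of all 3 libraries reflect the amplified chromosomes of MCF-7, chromosomes 1, 3, 17 and 20 were left out: 337 such regions remained, the ratios for the pairs were 31.3, 11.7 and 14.5 in place of 29.5, 11.4 and 14.5, and 329 MTA3 peaks overlapped both others, against at most 218 and 261 in permutations within chromosomes and within rank groups that keep the overlap of MTA3 with each library. Amplification of these chromosomes is therefore not the whole cause of the overlap. For the excess on chromosome 20, with 9.36% of the shared regions, amplified DNA and shared binding cannot be told apart, because no copy number or input reads were used here. A common control, if the same input served all 3 libraries, would also add shared peaks, and its share was not estimated. Leaving out the 142 blocks gave 467 regions of all 3, and leaving out the 750 highest GATA3 peaks gave 509.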
